A study of Nostoc sp. PCC 7120 = FACHB-418 with 24 samples.

How the data were processed

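RNA from wild-type Nostoc sp. PCC7120 was sequenced as stranded total RNA libraries after depletion of ribosomal RNA. Cells were grown at 30 °C either with 6 mM NH4Cl or, after washing, without combined nitrogen for 9 h, and rifampicin was added to 500 µg/ml. Per the labels, 23 fmol of a PhiX spike-in mix was added per 1 µg of total RNA. The submitters' processing notes name FastQC, BWA, SAMtools, featureCounts and DESeq2, without versions, settings or the step each was used for.

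The deposited files hold a signal, the mean read coverage in bins of 25 nt on each strand of the chromosome, which the authors had divided by 1 number per library. That number was recovered from the smallest step between values, and multiplying by it gave whole numbers of covered bases in 100% of the bins of every library, within a tolerance of 0.05. The 24 libraries carried 16 distinct divisors, and 8 divisors occurred in 2 libraries each. What the divisors were computed from is not stated, so they were undone and used only as an alternative. Plasmids and PhiX were not used here. Undoing the divisors gave a mean coverage of 92.7 to 194 per position and strand in each library. The bins give coverage and not read counts, so no counting interval was computed.

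Coverage was averaged over each of 5367 genes of the ASM970v1 annotation on the chromosome, which is 6413771 bp long, on the gene's own strand; 1 gene across the origin was left out. Positions count from 1. The strand came from the older locus tag for 4821 genes and from the stronger coverage for 546. Where the tag gave the strand and coverage was above 10, the stronger strand was the tagged one in 92.7% of 4163 genes. Gene symbols come from the annotation. For locus tags without one (nrrA, devA, cpcB and others), the names used in the literature were fixed with the gene lists before the data were examined.

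Levels before rifampicin were compared on coverage scaled by trimmed means (TMM, trimming 30% of ratios and 5% of levels), computed directly. The design had foreseen PhiX scaling after rifampicin and, without it, annotated stable RNAs, which were used here: the coverage of each library was scaled by the summed coverage of tRNA, tmRNA and RNase P RNA. The tmRNA gene ssrA made up 86.5% to 90% of that sum and rnpB, the RNase P RNA, 9.86% to 13.2%, so the scaling is in effect one on tmRNA. It assumes that tmRNA was stable over the time course. Scaling by total RNA levels would make every slope relative to the average gene.

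Genes with a mean scaled coverage of at least 10 over the libraries of a fit were tested on log2(coverage + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend, two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, at 0.05. For levels before rifampicin and for the change at 1 min, the 8 libraries at 0 and 1 min formed 4 groups of 2, with 4 residual degrees of freedom. For decay, the 20 libraries from 0 to 10 min were fitted with a start level and a slope per minute for each nitrogen condition, with 16 residual degrees of freedom. A half-life is minus 1 over the slope in log2 units per minute and was computed where the slope was below 0 past the threshold. The labels do not say whether equal replicate numbers mark 1 culture, so libraries were not paired. The p-values measure spread between these libraries only, and after 1 min each time point had 1 library per condition. To the residual degrees of freedom limma adds others shared over genes. Their median was 6.2 in the fit before rifampicin and 7.3 in the decay fit.

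Before the data were examined, 20 gene lists with at least 3 tested members were fixed by locus tag or by symbol. Lists of toxin-antitoxin genes and of stable RNAs had also been planned, but were not tested as lists. Lists were tested with camera, with the preset inter-gene correlation of 0.01 and with an estimated one, and with fry. With an estimated correlation camera also takes the residual degrees of freedom of the fit, 4 before rifampicin and 16 for slopes. A call lost there may reflect these few degrees of freedom as well as correlation between genes. For slopes the rank form of camera was used on their moderated t statistics. The rank of a gene thus reflects the noise of its slope as well as the size. Named genes followed a rule fixed beforehand: the 8 largest rises and falls before rifampicin past the threshold, above the median level and of like direction in both same-numbered library pairs; up to 3 members of each list by adjusted p; the 6 shortest and 6 longest half-lives per condition among protein-coding genes above the median level; the 6 largest slope differences past the threshold above that level, and the 6 largest changes at 1 min, in each direction; and always hetR, ntcA, nifH, glnA, devA, cpcB, rbcL and psbA where measured. Genes with near-identical copies are named only as uncertain.

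The delay of decline along genes was measured in genes of at least 2 kb with a coverage of at least 10, as the slope, in log2 per kb, of the 1 and 2 min level relative to 0 min over windows of 250 nt, with a two-sided exact sign test over genes. Coverage on the strand opposite to a gene and in gaps of at least 100 nt between genes was tested as the levels before rifampicin were. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

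The fits were tested on simulated data. Of genes given a 2-fold change before rifampicin, 99 of 100 were called, and 95 of 100 of those given a 4-fold change. There were 20 false calls in 4589 genes. Among all calls of this simulation that is a larger share than the threshold of 0.05 allows. Half-lives set at 2, 4 and 8 min came back as 2.01, 4.02 and 7.82 min. The simulated genes for decay all had a level of at least 100, and no pseudocount, floor or lag before decline acted on them. In all these simulations noise was drawn for each gene and library on its own. Shifts common to most genes of a library, as between the 0 min libraries of N deficiency, were absent. Recovery for real genes near the floor or with a delayed start was therefore not tested. A half-life doubled in 1 condition was called in 60 of 67 genes from 2 min and in 31 of 65 from 4 min. From 8 min it was called in 4 of 68, so differences among slowly decaying mRNAs are mostly out of reach of this design. The 6 false calls hold for independent noise only. Splits of the real libraries within time points gave up to 524 genes. A delay set at 0.4 log2 per kb came back as 0.394, without a pseudocount. This gradient is far above the 0.091 (ammonium) and 0.082 (N deficiency) measured at 1 and 2 min.

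Alternatives covered other scalings (median of ratios, stable RNA, TMM, the deposited divisors, RNase P RNA alone, and a mean of tmRNA, RNase P RNA and 6S RNA), other pseudocounts and level filters, limma without a trend, other time windows, a replicate block, and leaving out single libraries or time courses.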

Results

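Nostoc sp. PCC7120 is a filamentous cyanobacterium in which some cells differentiate into heterocysts, thick-walled cells that fix nitrogen, when combined nitrogen runs out. The series followed RNA after addition of rifampicin, which blocks the start of transcription by bacterial RNA polymerase, in cells kept in ammonium and in cells deprived of nitrogen for 9 h (N deficiency). The 24 libraries comprised 12 per condition. At 0 min, before rifampicin, and at 1 min each condition had 2 libraries; at 0.5, 2, 4, 6, 8, 10, 15 and 30 min it had 1. Levels are the mean coverage per position of a gene after scaling, at a mean coverage of 92.7 to 194 per position and strand of the chromosome in each library. They are given as mean ± SD (n = 2) before rifampicin, and log2 changes as estimate ± SE from limma.

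The first comparison asks how RNA levels differed between the nitrogen conditions before rifampicin. Genes of the heterocyst envelope polysaccharide and of heterocyst respiration and most heterocyst regulators were higher in N deficiency. Genes of the phycobilisome, which is the light-harvesting antenna, of carbon fixation, of the ribosome and of the ATP synthase were lower. In all, 2785 of 4589 genes changed, 1331 upward and 1454 downward, and 475 rose and 353 fell by more than 2-fold.

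All 19 genes of the heterocyst polysaccharide list rose, also when adjusted over the list alone (19), with a median log2 change of 7.08. Most lie in 1 cluster on the plus strand. There rfbF (alr2825, positions 3441147 to 3441920), annotated as a sugar nucleotide gene, went from 0.694 ± 0.479 to 2090 ± 142, a log2 change of 10.3 ± 0.20 (adjusted p = 4.4e-11). Its neighbours alr2827 (9.82 ± 0.13), alr2833 (8.83 ± 0.13), alr2828 (8.35 ± 0.32), lhgO (alr2826; 7.93 ± 0.10), alr2829 (7.83 ± 0.19) and alr2832 (7.35 ± 0.18) are the other members of the list among the 8 largest rises; alr2831 rose by 6.69 ± 0.09. The remaining gene of those 8, alr4984, went from 0.323 ± 0.307 to 303 ± 1.86 (7.86 ± 0.31). With ammonium levels this close to 0, the size of these folds depends on the pseudocount; 17 of the 19 list members stood under the minimum of 10 in ammonium, although no planned member was left out by it.

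Of the 15 heterocyst regulators, 11 rose, 2 fell (patA -2.00, patN -0.50) and 2 did not pass, and the counts adjusted over the list alone were the same 11 and 2. The response regulator gene nrrA (all4312) rose from 59.3 ± 7.29 to 2080 ± 99.3 (5.12 ± 0.09, adjusted p = 3.4e-11), and hetC (alr2817), an exporter gene needed early in differentiation, by 4.71 ± 0.15. Transcripts of ntcA, the global nitrogen regulator, rose by 1.99 ± 0.08 and those of hetR, the master regulator of heterocyst differentiation, by 1.47 ± 0.09 (716 to 1980, adjusted p = 1.6e-07). The list had a median of 1.47 and passed camera with the preset correlation (adjusted p = 3.01e-04), but not with an estimated one (adjusted p = 0.186 with an estimated correlation).

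Only 5 of the 20 planned heterocyst glycolipid genes were measured above the minimum, and all 5 rose, also adjusted over the list alone (5). Among them devB (alr3710; 5.13 ± 0.13), devC (alr3711; 4.30 ± 0.20) and devA (alr3712; 11.2 ± 0.739 to 185 ± 2.03, 3.93 ± 0.11) encode the exporter of the glycolipids. Of 17 planned nitrogenase and maturation genes, 4 were measured and all 4 rose (4 adjusted over the list alone), with nifZ (asr1408) at 5.17 ± 0.21, nifV (alr1407), the homocitrate synthase gene, at 4.60 ± 0.14 and nifT at 4.57 ± 0.21. In these 2 lists the level minimum itself favoured rises: devB, devC, all5342 and the 4 nitrogenase genes stood under the minimum of 10 in ammonium and were tested only because of their level in N deficiency. The nitrogenase structural gene nifH was under the minimum, at 4.36 and 4.48 in ammonium and 5.51 and 5.86 in N deficiency. All 8 measured genes of heterocyst respiration and oxygen protection rose (8 adjusted over the list alone), led by the cytochrome oxidase genes coxB2 (alr2514; 5.83 ± 0.15), coxC2 (alr2516; 5.82 ± 0.20) and coxA2 (alr2515; 5.44 ± 0.11); coxB2, coxC2, coxB3 and coxA3 were likewise under the minimum in ammonium. Camera with the preset correlation passed the respiration list (adjusted p = 2.36e-06; adjusted p = 0.164 with an estimated correlation); the glycolipid and nitrogenase lists passed too, and how much the minimum contributed was not tested (adjusted p = 0.164 and 0.186 with an estimated correlation).

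In nitrogen assimilation and transport, 15 of 19 genes rose, 2 fell and 2 did not pass (15 and 2 adjusted over the list alone). The ammonium transporter genes amt4 (alr0990; 279 ± 1.27 to 1380 ± 5.29, 2.31 ± 0.07) and amt1 (alr0991; 1.39 ± 0.08) rose, as did glnA, the glutamine synthetase gene, by 0.36 ± 0.10 (adjusted p = 0.013). The gene gifA (asl2329), for a protein that inactivates glutamine synthetase, fell by 4.46 ± 0.12, from 1490 ± 10.3 to 67.2 ± 10.2. The median was 0.77, at adjusted p = 0.00799 with the preset and adjusted p = 0.186 with an estimated correlation.

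All 21 phycobilisome genes fell, also adjusted over the list alone (21), with a median of -2.70. The phycoerythrocyanin operon fell furthest, with pecF (alr0527) at -4.46 ± 0.20, pecE (alr0526) at -4.34 ± 0.10, pecB (alr0523; 11900 ± 211 to 609 ± 7.30) at -4.28 ± 0.08, pecA (alr0524) at -4.11 ± 0.10 and pecC (alr0525) at -4.00 ± 0.09. The phycocyanin gene cpcB (alr0528) went from 98800 to 12900 (-2.94 ± 0.15). Of 11 measured carbon fixation and uptake genes 9 fell and 2 did not pass (9 adjusted over the list alone), with ccmN (all0864), for a carboxysome protein, at -2.30 ± 0.13 and the Rubisco subunit genes rbcS (alr1526) at -2.02 ± 0.11 and rbcL (alr1524) at -1.76 ± 0.11. Both lists passed the preset camera test (adjusted p = 2.18e-14 and 5.39e-05), and neither kept that call (adjusted p = 0.186 for each with an estimated correlation). The 2 largest falls outside the antenna and gifA were in short unnamed genes, PCC7120DELTA_RS32395 (610 ± 1.13 to 5.06 ± 1.91, -6.69 ± 0.18) and PCC7120DELTA_RS31805 (-4.69 ± 0.29). The strand of both was taken from the stronger coverage. Opposite PCC7120DELTA_RS31805 coverage rose from 3.15 and 1.54 to 111 and 109 (5.1 ± 0.24), so its direction depends on this choice of strand.

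Other housekeeping groups were lower as well. Of 53 ribosomal protein genes 48 fell and 5 did not pass (49 fell when adjusted over the list alone), as rpsQ (-2.76 ± 0.14), rplP (-2.57 ± 0.13) and rplV (-2.49 ± 0.12). All 6 ATP synthase genes fell (atpH -1.97 ± 0.12, atpA -1.89 ± 0.11), and so did all 9 of photosystem I (psaJ -1.06 ± 0.11). In photosystem II 23 of 29 genes fell, 2 rose and 4 did not pass, with psbD (alr4290) at -2.17 ± 0.11 and psbC (alr4291) at -1.85 ± 0.11. Of its 5 psbA copies, whose near-identical sequences leave single values uncertain, alr4866 went from 68500 to 39600 (-0.79 ± 0.16) and alr3742 rose (1.41 ± 0.12). In the NDH complex 5 of 6 genes fell, and 9 of 12 chaperone genes did, 3 not passing. Outside the ribosome list, counts adjusted over each list alone equalled those over all genes. Camera with the preset correlation gave adjusted p = 2.33e-13 (ribosome), 3.01e-04 (ATP synthase), 7.99e-04 (photosystem I), 1.59e-05 (photosystem II), 0.0354 (NDH) and 0.00782 (chaperones). The same tests gave adjusted p = 0.305, 0.303, 0.303, 0.186, 0.342 and 0.457 with an estimated correlation.

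Genes of the transcription and RNA decay machinery changed less or in both directions. Of 6 measured sigma factor genes sigC (2.44 ± 0.08), sigG (alr3280; 1.42 ± 0.09) and sigE (alr4249; 1.38 ± 0.14) rose, 2 fell and 1 did not pass (camera adjusted p = 0.223). The RNA polymerase gene rpoA (all4191) fell by 1.04 ± 0.12, rpoC2 (alr1596) was at -0.37 ± 0.08 (adjusted p = 0.0025) and rpoB was at 0.03 ± 0.08 (adjusted p = 0.73; list 0.244). Among the RNA degradation genes pnp (all4396), for polynucleotide phosphorylase, was at -0.31 ± 0.09 (adjusted p = 0.014), while rne (alr4331), for ribonuclease E, was at -0.08 ± 0.08 (adjusted p = 0.40) and rnhB (alr4332) at -0.09 ± 0.10 (list 0.473). Of 6 other ribonuclease genes 1 rose, 3 fell and 2 did not pass (list 0.362); of 14 translation factor genes 2 rose, 7 fell and 5 did not pass (3 rose adjusted over the list alone; list 0.223); of 3 transposase genes, uncertain because of copies, 1 fell (list 0.787).

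Of the 14 lists that passed camera with the preset correlation, the polysaccharide list alone passed with an estimated one (adjusted p = 6.37e-17 and 0.0137). Its estimated correlation was -0.0173, below the preset 0.01, so correlation between genes does not explain its larger p. The calls lost by the other lists can therefore not be put down to correlation alone. By fry, which tests a list against no change and not against other genes, 18 of the 20 lists passed, among them sigma factors (adjusted p = 1.65e-05), RNA polymerase core (adjusted p = 0.0112), ribonucleases (adjusted p = 0.0202) and translation factors (adjusted p = 0.0083), but not RNA degradation (adjusted p = 0.148) or transposases (adjusted p = 0.235). The median change of all genes was -0.01 in this fit and moved to -0.31 with a scaling on tmRNA, RNase P RNA and 6S RNA, and to 0.27 with the deposited divisors; the latter left 854 genes, 670 higher and 184 lower. The median of each of the 14 lists kept its sign under all 5 other scalings.

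**Figure D1:**
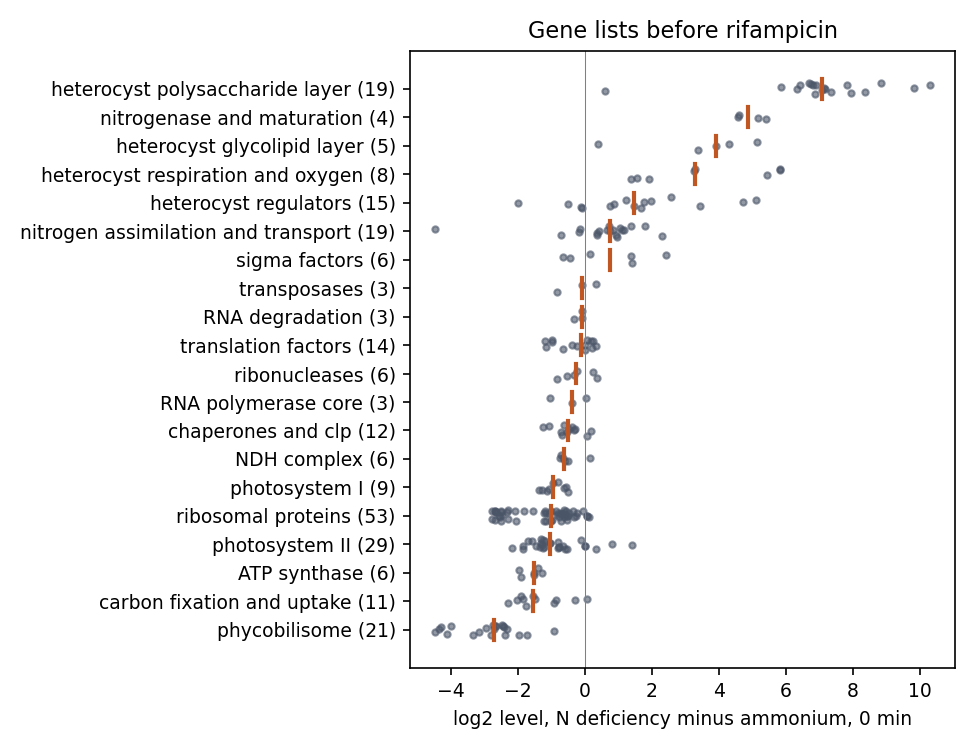
Log2 level in N deficiency minus ammonium before rifampicin (x axis) for the measured members of the 20 gene lists (y axis, number of members in brackets); each point is a gene and each bar the median of its list. List medians run from -2.70 for the phycobilisome to 7.08 for the heterocyst polysaccharide layer.

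The second comparison asks how fast each mRNA declined once initiation was blocked. In ammonium 3738 of 4383 genes declined and 90 rose relative to the stable RNAs, and in N deficiency 3801 declined and 98 rose. The median half-life over protein-coding genes was 3.87 min in ammonium (quartiles 2.42 and 7.23, 3660 genes) and 4.53 min in N deficiency (2.79 and 8.17, 3723 genes). Over all genes the medians were 3.82 and 4.48 min; the time courses fitted singly gave 3.39 and 3.63 min in ammonium and 4.35 and 3.92 min in N deficiency, at different sampling times. Of the starting level, the median gene kept 57.9% at 4 min, 36.2% at 8 min and 12.5% at 15 min in ammonium, and 72.9%, 38.6% and 16.4% in N deficiency, each from 1 library. The start in N deficiency is the mean of 2 libraries that stood at 118% and 84.9% of it themselves, so these shares depend on the baseline.

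**Figure D2:**
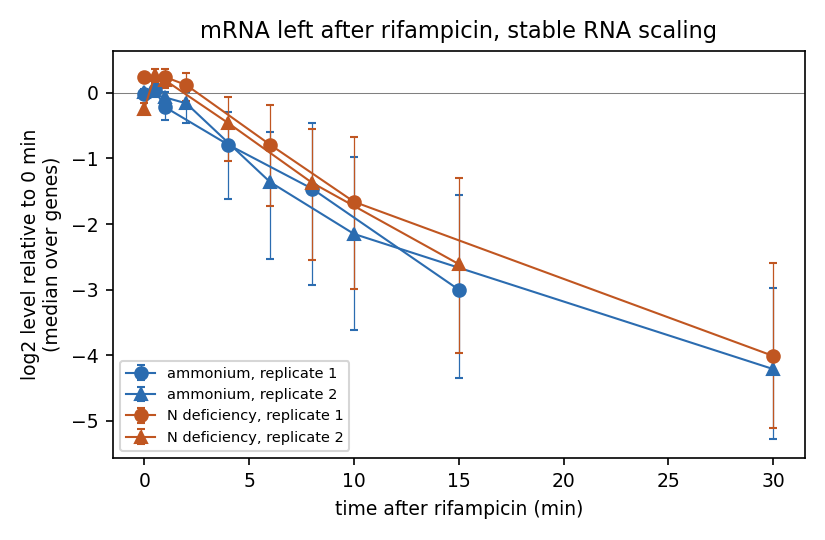
Median log2 level of 4289 protein-coding genes relative to the mean of the 0 min libraries of the same condition (y axis) against time after rifampicin in min (x axis), scaled to stable RNAs; each point is 1 library and bars span the quartiles over genes. At 30 min the medians were -4.21 in ammonium and -4.01 in N deficiency.

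Among the shortest half-lives above the median level were all2072 (annotated as thrC, threonine synthase; 1.26 min), all2303 (1.26), asr0581 (1.31), alr2872 (1.33), alr5005 (1.34) and alr2616 (1.34) in ammonium. In N deficiency they were all2747 (1.28 min), patS (1.29), the gene of the peptide that inhibits heterocyst differentiation, asl4014 (1.30), all2303 (1.30), asl1496 (1.31) and asr0923 (1.33). At the other end stood all4131 (34.4 min), alr3355 (34.2), alr3844 (33.4), asr4648 (32.7), all2003 (31.2) and PCC7120DELTA_RS07075 (30.6) in ammonium. In N deficiency these were PCC7120DELTA_RS31130 (39.2 min), the aldolase gene fba (34.4), PCC7120DELTA_RS07640 (33.7), alr0225 (33.5), nuoH (33.1) and alr2359 (32.7). Half-lives this long exceed the 10 min window, and the slopes barely pass the threshold (all4131 -0.029 ± 0.013 per min, adjusted p = 0.043). Without replicate 2 of ammonium the all4131 slope was 1e-04 and that of alr3844 0.0051.

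Most heterocyst regulator mRNAs had short half-lives, but not all. In ammonium and N deficiency hetR had half-lives of 2.74 and 3.49 min, nrrA of 2.71 and 3.65 min and patS of 2.00 and 1.29 min, against 5.61 and 13.6 min for ntcA and 11.1 and 20.4 min for devH. The heterocyst regulators as a list (14 and 15 of 15 declining, median 2.75 and 3.49 min) ranked toward faster decline by t statistic in ammonium (rank camera, adjusted p = 0.0458). In N deficiency the list did not pass (adjusted p = 0.0697), and in neither condition did it keep a call (adjusted p = 0.72 and 0.751 with an estimated correlation). The difference between the conditions did not pass (adjusted p = 0.284). Many phycobilisome, ribosomal protein and carbon fixation mRNAs had shallow slopes. In the ribosomal cluster the slope also followed position. In the order of transcription, ammonium slopes were -0.168 (rplC), -0.083 (rplD), -0.054 (rplB), -0.022 (rpsS) and 0.008 (rplV) per min. From there the list members stayed above 0 up to rpsE (0.067). How far position enters the half-lives of these lists was not tested. Only 5 of 21 phycobilisome genes declined in ammonium and 11 in N deficiency, with medians of 22.7 and 17.7 min among those (adjusted p = 1.94e-07 and 1.59e-05); cpcB had a slope of -0.006 ± 0.014 per min in ammonium (adjusted p = 0.69). Of 53 ribosomal protein genes 29 declined in each condition (median 9.80 and 9.90 min; adjusted p = 1.02e-08 and 5.75e-07), and of 11 carbon fixation genes 4 and 8 (15.9 and 14.7 min; adjusted p = 4.17e-04 and 0.00186). None of these 3 lists kept its call (adjusted p = 0.412 in ammonium and adjusted p = 0.466 in N deficiency with an estimated correlation). For glnA the slope was -0.008 ± 0.016 in ammonium (adjusted p = 0.65) and the half-life 21.4 min in N deficiency, and for rbcL -0.036 ± 0.017 (adjusted p = 0.051) and 19.6 min.

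Of the other lists, t statistics ranked toward slower decline in both conditions for the polysaccharide list, heterocyst respiration, nitrogen assimilation, RNA polymerase core, photosystem I, photosystem II, ATP synthase and the NDH complex. The nitrogenase list was called in ammonium (rank camera, adjusted p = 0.0258, against 0.391 in N deficiency). Rank and slope can part: transposases in ammonium ranked toward slower decline, without passing, at a median slope of -0.4524 against -0.219 over all genes. Position may enter here too, as ammonium slopes ran from -0.117 (nirA) to 0.081 (nrtD) along 1 gene cluster. The members named above of the polysaccharide, nitrogenase and respiration lists stood near the floor in ammonium, where the pseudocount flattens slopes. Neither the glycolipid list (median 6.95 and 5.95 min), sigma factors (7.01 and 5.15), RNA degradation (7.06 and 7.94), chaperones (7.87 and 9.14), transposases (2.17 and 2.45), ribonucleases (2.18 and 3.55) nor translation factors (6.01 and 6.71) passed. Of 13 lists called in ammonium and 11 in N deficiency, 0 kept the call (lowest adjusted p = 0.412 and 0.466 with an estimated correlation). Scaled by TMM, 1645 and 1497 genes declined, since slopes are then relative to the average gene by construction.

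**Figure D3:**
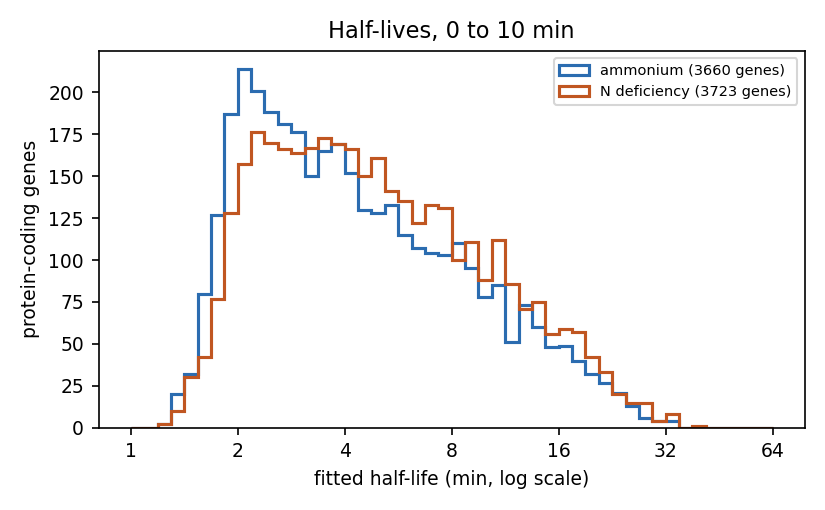
Number of protein-coding genes (y axis) by fitted half-life in min (x axis, log scale) in ammonium and in N deficiency, from the 20 libraries between 0 and 10 min. The medians were 3.87 and 4.53 min.

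The third comparison asks which mRNAs declined at different rates in the 2 conditions. Half-lives ranked genes alike (Spearman's rho = 0.917 and Pearson's r of the logarithms = 0.905 across 3513 genes with both, which are not independent replicates). In 66% of these genes the half-life was longer in N deficiency, with a median ratio of 1.09, a share not tested across cultures. The slope differed in 247 of 4383 genes, 187 slower and 60 faster in N deficiency, or 286 and 53 with a pseudocount 5 times smaller and 120 and 91 with one 5 times larger; 53 of the 187 were under a level of 50 in N deficiency. The clearest slower decline was in all4376, from 1.98 to 9.25 min (slope difference 0.398 ± 0.034 per min, adjusted p = 1.1e-07), whose level before rifampicin was also higher in N deficiency (220 and 1070). The gene all1694 (annotated as lipA; 1.78 to 4.34 min, 0.330 ± 0.039), asr1314 (2.06 to 5.87 min, 0.314 ± 0.054), alr5226 (1.92 to 4.63 min, 0.303 ± 0.037) and alr4839 (1.53 to 2.84 min, 0.303 ± 0.043) followed, and ntcA went from 5.61 to 13.6 min (0.105 ± 0.023, adjusted p = 0.008). With the 0 to 30 min window the difference of alr5226 was -0.0012. PCC7120DELTA_RS31805 had the largest difference (0.418 ± 0.086), at a level of only 5.65 in N deficiency and on a strand taken from coverage.

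Faster in N deficiency were alr4984 (half-life 1.82 min in N deficiency; slope difference -0.508 ± 0.049), the envelope polysaccharide gene hepB (alr3698; 6.98 to 1.60 min, -0.482 ± 0.057), alr0744 (-0.408 ± 0.059), all0059 (-0.385 ± 0.058), alr3676 (-0.334 ± 0.052) and alr2208 (-0.282 ± 0.070). All 6 stood between 0.323 and 12.9 in ammonium, near the floor where the pseudocount flattens a slope. The psbA copy alr4592, uncertain as above, had a faster decline from a level of 239 and 104 (-0.238 ± 0.038, adjusted p = 5.9e-04). The regulators patS (-0.278 ± 0.058, adjusted p = 0.0057) and hetC (alr2817; -0.464 ± 0.051) declined faster as well, from ammonium levels of 24.7 and 1.75. For hetR the difference was 0.078 ± 0.034 (adjusted p = 0.20), and for devA -0.036 ± 0.038 (adjusted p = 0.65). By the t statistic of the difference, the phycobilisome, ribosomal protein and carbon fixation lists ranked toward faster decline in N deficiency (rank camera, adjusted p = 4.79e-04, 4.79e-04 and 0.0214). None kept the call (adjusted p = 0.824 for each with an estimated correlation), and their median slope differences were only -0.0163, -0.0077 and -0.0165 per min. The ranking is relative to all genes tested, whose median difference was 0.018 per min. Without the 0 min library of N deficiency replicate 2 that median was 0.001, and the lists were not tested again without it.

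Chance could not be excluded for the count: with start levels removed the real split gave 254 genes, and 12 of 100 splits of the libraries within time points, the real one included, gave as many, up to 524. One library weighs on it too, because without the 0 min library of N deficiency replicate 2 the count was 443, of which 242 were faster in N deficiency, and the share of genes with a longer half-life was 53.8%. Without the first minute it was 49.4%, and leaving out replicate 1 or 2 of ammonium gave 134 and 60 genes, of N deficiency 35 and 97.

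The fourth comparison asks what changed within 1 min of rifampicin. In ammonium 238 genes fell and 1, PCC7120DELTA_RS02810, rose (0.85 ± 0.28), of 4601 tested; in N deficiency 33 fell and 4 rose. Transfer RNA genes were prominent: 23 of 33 fell in ammonium and 17 in N deficiency, against 211 and 14 of 4498 protein-coding genes. The deepest falls in ammonium were in asr1661 (-3.42 ± 0.24, adjusted p = 3.5e-43), asr2172 (-2.68 ± 0.29), the tRNA genes allrt07 (-2.62 ± 0.24), allrt23 (-2.59 ± 0.30) and allrt13 (-2.55 ± 0.23), and all1164 (-2.53 ± 0.20). In N deficiency they were in the tRNA gene allrt17 (-2.16 ± 0.28), asr1661 (-1.91 ± 0.24), and the tRNA genes allrt14 (-1.63 ± 0.25), allrt13 (-1.58 ± 0.23), allrt05 (-1.58 ± 0.30) and allrt09 (-1.52 ± 0.28). The rises in N deficiency were in PCC7120DELTA_RS33590 (1.22 ± 0.31), the psbA copy all3572 (1.00 ± 0.22), all4644 (0.89 ± 0.22) and the ribosomal protein gene rpmJ (0.69 ± 0.19). An adjusted p as small as that of asr1661 cannot come from so few libraries gene by gene, so it rests on a spread shared over genes. Between the 0 min libraries of N deficiency the median gene differed by -0.47 log2 under this scaling, a shift common to most genes. The counts at 1 min therefore do not measure replicate spread of single genes.

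These counts moved with single libraries left out, where the group concerned keeps 1 library and the spread comes from the other groups. Without 1 of the 0 min libraries of N deficiency, replicate 1 or 2, N deficiency gave 2570 (2518 of them rises) or 9 genes and ammonium 476 or 479, and all3572 was at -0.05 without replicate 2. Without 1 of the 1 min libraries of N deficiency, replicate 1 or 2, N deficiency gave 16 or 14 genes and ammonium 146 or 149. Leaving out ammonium libraries gave 82 and 80 genes in ammonium and 23 in N deficiency (0 min, replicate 1 and 2), and 68 in ammonium without the 1 min library of replicate 1.

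The fifth comparison asks whether decline started later farther from the start of long genes. In ammonium 240 of 317 genes of at least 2 kb (75.7%) kept more of their 3′ part at 1 and 2 min, with a median of 0.091 log2 per kb (exact sign test, p = 1.2e-20), and in N deficiency 240 of 342 (70.2%; 0.082 log2 per kb, p = 5.8e-14). In genes of at least 3 kb the medians were lower, at 0.053 (exact sign test, p = 1.1e-05) and 0.045 log2 per kb (p = 0.0035). The gradient was absent at 0.5 min (-0.001 and 0.01 log2 per kb; exact sign test, p = 0.82 and 0.26) and steeper at 4 min (0.392 and 0.327 log2 per kb in 87.4% and 83.0% of the genes). Between the 0 min replicates, which give the background, it was 0.007 in ammonium (exact sign test, p = 0.37) and -0.017 in N deficiency (p = 0.089). At 4 min in ammonium the median level was 40.9% of the start in the first 250 nt and 75.2% between 1750 and 2000 nt. Over 309 genes measured in both conditions the gradient was lower in N deficiency, by a median of -0.022 log2 per kb (exact sign test, p = 0.03), a call lost with the level filter 5 times stricter (-0.007, p = 0.56) and in genes of at least 3 kb (-0.008, p = 0.31). Genes of 1 operon are not independent, which the sign test does not take into account, and without the 2 min library (replicate 2 in ammonium, replicate 1 in N deficiency) the medians were 0.058 and 0.048.

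**Figure D4:**
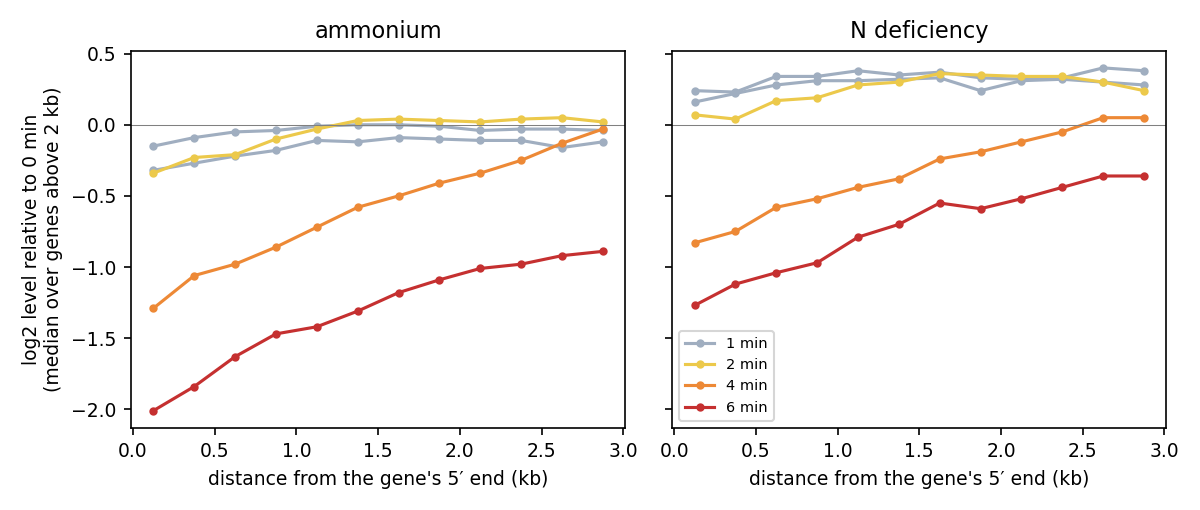
Median log2 level relative to 0 min (y axis) against distance from the 5′ end in kb (x axis) over genes of at least 2 kb, at 1, 2, 4 and 6 min in ammonium (left) and N deficiency (right); each line is 1 library. At 4 min in ammonium the first 250 nt were at -1.29 and the window from 1750 to 2000 nt at -0.41.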

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

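The tests of the pseudocount for the genes that declined faster, under a level of 50 and at 50 or more, and the test of the share of tmRNA were chosen only after the results they bear on had been seen, and the pseudocount tests replaced an earlier version whose result had been read. The other tests were fixed before.

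Decay slopes differed between the conditions in 247 genes, by a test of the difference itself. With start levels removed the real split gave 254 genes, 12 of 100 splits of the libraries within time points (the real one included) gave as many, and the highest other split gave 524, so chance cannot be excluded for this count. Of the 60 genes that declined faster in N deficiency, 33 were under a level of 50 in ammonium, and 18 of these were still called with a pseudocount 5 times smaller. Their median slope difference was -0.175 per min with the smaller, -0.204 with the usual and -0.241 with the larger pseudocount. Flattening of the ammonium slope near the floor may account for some of the calls, but most of the difference stayed, and the explanation is left open. For the 25 genes at 50 or more in both conditions the floor is not the whole cause, since 22 of them were called under both other pseudocounts; among them were era (slope difference -0.251 ± 0.033), cynS (-0.212 ± 0.030) and ribH (-0.188 ± 0.035).

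The 0 min library of N deficiency replicate 2 stood apart. Its median gene lay -0.47 log2 from replicate 1 (interquartile range 0.28), against 0.02 (0.20) in ammonium, and tmRNA held 9.50% of its coverage against 6.73%. The shift did not follow the decay slopes across genes (Spearman's rho -0.08, where 0.3 or more had been predicted for a later sampling time under the label 0 min). This argues only against a delay long enough for decay to set in. The test cannot judge a delay of 1 or 2 min, as the median gene then stood at 118%, 114% (1 min) and 109% (2 min) of its start. The slopes were also fitted with both 0 min libraries included. A higher share of tmRNA alone may explain part of the shift, since with RNase P RNA scaling the median was -0.16, just beyond the 0.15 set for it; but 6S RNA (ssrS) moved too, at 0.45 in this library and -0.45 in replicate 1 relative to the stable RNA sum, so tmRNA was not the only RNA that differed, and the explanation is left open. No biological explanation was tested, since the design names none for a single library.

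The change at 1 min differed between the conditions in 17 genes, always toward higher values in N deficiency, where 10 of them stood above 0, such as alr2838 (-0.99 in ammonium and 0.40) and asl2151 (-0.78 and 0.54). Others fell less, among them all1164 (-2.53 and -1.14), the signal recognition particle RNA gene ffs (-2.24 and -1.11) and alr1166 (-2.23 and -0.23). The median difference over all genes was 0.38 in the same direction. It was 0.04 with TMM, and 0.62 or 0.14 without the 0 min library of N deficiency replicate 1 or 2. The unadjusted count was 497. With a replicate block the adjusted count was 5. Scaled by TMM it was 0, and without the 0 min library of N deficiency replicate 1 or 2 it was 3099 or 0. Without any 1 of the other libraries it was 0 or 1, except 28 without the 1 min library of ammonium replicate 2, so the count is not stable to single libraries.

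For 3 gene lists (phycobilisome, ribosomal proteins, carbon fixation) the t statistics of the slope difference ranked apart from those of other genes, and for 0 with an estimated correlation.

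Coverage on the strand opposite to annotated genes, which the comparisons of genes do not use, was higher in N deficiency at 442 and lower at 202 of 1645 genes tested (limma, same test as for genes; 790 unadjusted). The largest rises were opposite alr3771 (2.09 and 1.44 in ammonium, 173 and 212 in N deficiency), all2842, alr2570 and alr4311. The last of these lies next to nrrA (all4312), transcribed on that other strand, whose mRNA rose. Opposite glnA (alr2328, positions 2807483 to 2808907) coverage fell by 3.14 ± 0.22, from 120 and 108 to 9.29 and 15.3; the neighbouring gifA, which is read from that strand, fell by 4.46.

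Gaps of at least 100 nt between genes, tested on each strand, were higher in N deficiency at 757 and lower at 866 of 3646 strands (1862 unadjusted). The largest rises lay inside the polysaccharide cluster, as between alr2825 and alr2826 (8.14 ± 0.36). Among the falls were both gaps around PCC7120DELTA_RS32395 (-5.55 ± 0.32 and -4.67 ± 0.32) and the one between pecF (alr0527) and cpcB (alr0528), from 56900 and 54400 to 6110 and 4180 (-3.46 ± 0.18).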

How the results depend on the processing

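Settings that use the deposited divisors, RNase P RNA or the mean of tmRNA, RNase P RNA and 6S RNA, other pseudocounts for slopes, the library left out for standing apart, all settings of the difference at 1 min, the estimated correlation for slopes and, for the gradient, the libraries left out and the settings of its difference between conditions were chosen only after the results had been seen. Where not stated, the cause was not tested.

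Before rifampicin 2785 genes changed, and 14 of 16 alternatives stayed within 1.5 times that count. Among these, stable RNA scaling gave 1904 (949 higher, 955 lower) and a replicate block 2819. RNase P RNA scaling, also within that range, gave 2566 with another split (845 higher, 1721 lower). The count was 854 with the deposited divisors (670 higher, 184 lower) and 1615 with the mean of 3 RNAs (457 higher, 1158 lower). Lists called fell from 14 to 1 with an estimated correlation, which also lowers the degrees of freedom, and were 14 with the block. Of 79 genes named in this comparison, 0 of 1259 values reversed and 36 lost the threshold.

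The counts of declining genes (3738 and 3801) stayed within 1.5 times in 15 of 16 alternatives and were 1645 and 1497 with TMM, where slopes are relative by construction; a block gave 3721 and 3837. Each median half-life covers only genes called as declining in that condition, so the gene sets differ. Without replicate 2 of ammonium, median slopes over all tested genes were -0.19 in ammonium and -0.192 in N deficiency. For 1 to 10 min they were -0.209 and -0.207, and the median ratio in genes with both half-lives was 0.995. With this limit, the median half-life was longer in N deficiency in all 16 alternatives. In ammonium and N deficiency it was 4.59 and 5.27 min with TMM, 3.24 and 3.82 for 0 to 6 min, 6.43 and 6.5 for 0 to 30 min, 3.42 and 3.92 with the deposited divisors, 4.7 and 5.12 with the larger pseudocount, 3.8 and 4.44 with a block. In ammonium it was also 4.06 without the filter, 3.65 with the mean of 3 RNAs and 3.65 with the smaller pseudocount. Leaving out a time course gave 3.39 to 3.93 min in ammonium and 3.92 to 4.43 in N deficiency. The share of genes with the longer half-life in N deficiency ran up to 85.3% (0 to 6 min) and reversed to 49.4% for 1 to 10 min. Lists called by slope went from 24 to 0 with an estimated correlation, which lowers the degrees of freedom there too.

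The count of slope differences (247, of which 187 slower in N deficiency) was 1164 with TMM (528 slower, 636 faster), 339 with the smaller pseudocount (286 slower, 53 faster), 211 with the larger (120 slower, 91 faster), 152 for 0 to 6 min, 116 for 1 to 10 min (49 slower, 67 faster), 68 for 0 to 30 min, 99 with the deposited divisors, 54 with the mean of 3 RNAs, 218 with a block and 443 without the 0 min library of N deficiency replicate 2; leaving out a time course gave 35 to 134.

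At 1 min the counts (239 and 37) were 380 and 16 with the deposited divisors, 438 and 64 with RNase P RNA (24 of the 64 rises, against 4 of 37), 184 and 31 with a block; leaving out a library, which leaves its group with 1, gave 68 to 479 and 9 to 2570 (2518 of these rises, against 4 of 37). The difference at 1 min (17) was 0 with TMM, 0 with the deposited divisors, 5 with a block and 0 to 3099 leaving out a library. The gene all3572 ran from -0.05 (reversed, without the 0 min library of N deficiency replicate 2) to 2.05 (without that of replicate 1) in N deficiency.

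Single slopes that reversed with TMM did so by that construction. In ammonium these were PCC7120DELTA_RS07075 (0.204), all2003 (0.205), all3572 (0.218), all4131 (0.208), alr0528 (0.231), alr1524 (0.201), alr3355 (0.208), alr3712 (0.0758), alr3727 (0.206), alr3742 (0.126), alr3844 (0.207), alr4592 (0.162), asr4648 (0.206), glnA (0.229) and ntcA (0.0578). In N deficiency they were PCC7120DELTA_RS07640 (0.186), PCC7120DELTA_RS31130 (0.19), all3572 (0.109), alr0225 (0.186), alr0528 (0.166), alr1524 (0.165), alr2359 (0.185), alr3712 (0.046), alr3727 (0.0814), alr3742 (0.165), alr4866 (0.16), fba (0.187), glnA (0.169), ntcA (0.142) and nuoH (0.186). For 0 to 30 min the slope of alr4866 in ammonium was -0.0186 and the difference of alr5226 -0.0012. Leaving out a time course, the ammonium slope of all4131 ran from -0.0424 to 1e-04 and that of alr3844 from -0.0504 to 0.0051, both reversed without replicate 2 of ammonium.

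The gradient along genes kept its direction and threshold in all 7 alternatives per condition, from 0.053 to 0.116 log2 per kb in ammonium and 0.045 to 0.102 in N deficiency, lowest in both with the 3 kb minimum. The difference of the gradients (-0.022) lost its call with the level filter 5 times stricter (-0.007) and the 3 kb minimum (-0.008). Replicate deviations did not correlate across conditions (Pearson's r across genes 0.01 and 0) but did within them (0.20 and 0.18). The main fits treat same-numbered libraries as independent and so leave this out. In the fit at 0 and 1 min the replicate block was a single term shared by both conditions, so it does not take up a correlation within them. Pairing within each condition was not tested there. The decay fit had a separate block for each condition. Depth was not varied. In simulated data without a floor, a pseudocount or shifts shared by the genes of a library, 4 of 68 half-lives doubled from 8 min were called, against 60 of 67 from 2 min.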

Other observations

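The test of gene pairs was fixed before its result was seen.

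Several RNAs usually counted as stable did not behave so in these libraries. Of 29 tRNA genes above the minimum, 28 declined in ammonium and 27 in N deficiency over 10 min, and ffs, the signal recognition particle RNA, stood at -2.41 and -2.07 log2 after 1 min in ammonium and at -1.19 and -1.04 in N deficiency, relative to tmRNA and RNase P RNA. All tRNA coverage together made up at most 0.25% of the scaling sum. Library preparation from total RNA recovers mature tRNA poorly, so this signal cannot be read as the level of mature tRNA; whether it comes from precursors was not tested.

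The median gene in N deficiency stood at 118% of its start at 1 min in replicate 1 and 114% in replicate 2, and at 109% at 2 min, against 86.1% and 95.2% at 1 min and 89.5% at 2 min in ammonium. The start is the mean of both 0 min libraries, and in N deficiency these stood at 118% (replicate 1) and 84.9% (replicate 2) of it themselves, so the median of replicate 1 did not change between 0 and 1 min.

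Divisors shared by 2 libraries always joined 1 library of each condition with the same replicate number, such as the 0 min libraries of replicate 2 (0.855 for both), although the time points in a pair mostly differed. The values are given as found.

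A hypothesis for the gradient along long genes is that polymerases already past the promoter run on to the end after initiation is blocked, so that distal sequence is still made for minutes. It predicts that in pairs of adjacent genes on 1 strand, both under 2 kb and at most 50 nt apart, the downstream gene keeps more of its level at 4 min. This held in 65.6% of 567 pairs in ammonium (exact sign test, p = 9.2e-14) and in 66.9% of 589 in N deficiency (p = 1.8e-16), against 52% of 394 (p = 0.45) and 51.9% of 422 pairs (p = 0.47) more than 300 nt apart. The result is consistent with run-on transcription; a 5′ to 3′ order of decay may give the same gradient, and these data do not separate them. Pairs of 1 operon are not independent.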
